A study of Mus musculus with 4 samples.

How the data were processed

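Total RNA from primary calvarial osteoblast cultures was measured on 4 Affymetrix Mouse Gene ST arrays, which read each transcript cluster with many probes along its length. Per the labels' protocols, osteoblast progenitors from newborn mouse calvaria were kept in osteogenic medium for 21 days, and the labelled cDNA of each culture was hybridised to its own array. The labels put 2 arrays in the Runx3f/f/Col1a1-cre group and 2 in the wild-type group and call them biological replicates 1 and 2 of each. The tissue tag of all 4 arrays reads myoblast, whereas the cell type tag and titles read osteoblast; the titles were followed. The design text speaks of purified progenitors while the growth protocol describes differentiated cultures, so the stage at which RNA was taken rests on the growth protocol.

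The deposited values are taken to be on a log2 scale, since the submitters' processing notes name Partek and RMA, without version, role or order, and the values run from 2.26 to 14.1 on the arrays. The log base, the centring and the step at which arrays were combined are not given in the sources used here, so every fold below assumes base 2. Median values over all 41345 rows were 5.50 and 5.45 on the mutant and wild-type arrays of replicate 1, and 6.08 and 6.05 on those of replicate 2. Mutant and wild-type arrays of the same replicate number held exactly equal values (no tolerance) in 15613 rows (37.8%) for replicate 1 and 18665 rows (45.1%) for replicate 2, and no other pair of arrays shared a value in any row. How the arrays of a replicate number came to share values is not given in the sources used here. They were taken to have been processed together by the authors, which makes the replicate number a possible processing batch. It was not a term of the main fit but a block in alternatives. Differences within each replicate are printed beside pooled ones for some genes and lists.

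Rows were named through the platform annotation supplied with the values. Of the rows, 23521 had 1 gene symbol, 1814 had several and 16010 had none listed; only rows with 1 symbol were named or tested. For the 22180 genes so named, the probe set with the highest mean level stood for the gene. A gene was tested when at least 2 of the 4 arrays lay above 4.71, the 90th percentile of the mean levels of 1405 olfactory and vomeronasal receptor rows, which left 17841 genes (80.4%). Runx2 and Spp1 were not analysed here, having no row of their own with a single symbol.

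The comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, group as the only term, all 4 arrays), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A second description took unadjusted p under 0.05 with at least a 1.5-fold difference, and another, added after the data were examined, took genes at least 1.5-fold apart in the same direction within both replicates. Gene lists (39 lists, 955 of 1079 entries matched to a named row) were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the lists; camera with an estimated correlation, camera on ranks and fry (with statmod 1.5.0 installed) were alternatives. Groups, lists, tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named Runx3 and its partners; per direction the 12 largest differences past the threshold whose arrays did not overlap, with unfilled places taken by genes at unadjusted p under 0.01; up to 4 members of each list described, by smallest p; and Col1a1, Alpl, Bglap, Ibsp and Sp7. Predicted genes, clone names and small RNAs were left out of the naming (23 higher and 5 lower).

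Alternatives covered the dim-gene filter, normalization, treatment of probe sets, inclusion of every row, the variance model, array weights, the replicate number as a block, each array left out, and other thresholds. Same-numbered arrays deviated together from their group means (Pearson r = 0.92 across genes, raised by the equal values). The labels do not say that a number marks a shared litter or day. The fit without the block was therefore kept as the main result and the block as an alternative. Without the block, the offset between replicate numbers stays in the residual spread.

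The fits were tested on simulated values for 17841 genes with 200 of them changed. Without the block, 0 of 100 genes changed by 1 log2 unit and 0 of 100 changed by 2 units passed the adjusted threshold, although 70 and 97 passed unadjusted p with 1.5-fold; with the block, 80 and 95 passed, beside 7 false calls. The intensity trend recovered 2 and 34. A list whose members were all lowered by 1 log2 unit was called in each fit and 0 of 38 unshifted lists were. The simulated noise was independent between genes, so false list calls from correlated genes were not tested. Residual spreads were shuffled between genes and no values were equal, so recovery on the real arrays may differ. On those, 0 genes passed with the block. The number of arrays limits the precision: 2 against 2 leaves 2 residual degrees of freedom, and an exact permutation test of such groups cannot go below p = 0.333. The labels call the replicates biological without naming animals or litters, so p-values measure the spread between these cultures and arrays. In the main fit that spread includes the offset between replicate numbers.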

Results

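Gene expression was compared between osteoblast cultures of mice carrying a Runx3 deletion driven by Col1a1-cre, which acts in cells that make type I collagen, and wild-type cultures, after 21 days in osteogenic medium. The series asked which part of the osteoblast programme depends on Runx3, a Runt-family transcription factor. Each group had 2 arrays. Median levels of the tested genes were 7.53 on both arrays of replicate 1 and 7.81 on both arrays of replicate 2, on the deposited log2 scale.

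Runx3 itself was not lower on the arrays labelled as mutant. Its single probe set read 7.94 and 8.06 there against 7.45 and 7.87 in wild type, a log2 difference of 0.34 (SE 0.20, limma adjusted p = 1), with 0.49 within replicate 1 and 0.19 within replicate 2. The labels do not give the deleted exons, so a probe set read along the whole gene may not check the deletion; the groups are therefore called mutant-labelled and wild type below. Runx1 differed by 0.07 and Cbfb, the shared partner of the Runt factors, by -0.03. The sign of both turned when single arrays were left out, which leaves the offset between replicates in the difference.

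At camera's preset correlation, lists of macrophage genes, mineralizing osteoblast genes and the cell cycle were lower on the mutant-labelled arrays, and the Notch list, led by Hes1, Hey1 and Hey2, was higher. With an estimated correlation all of these lost their call (adjusted p = 0.856), 0 cell cycle genes passed over their lists alone, and 0 Notch genes did so with the replicate block. That setting rests on 2 residual degrees of freedom, with the offset between replicates left in the residuals, and called 0 of 39 lists. Lists with medians of -1.34 (macrophage) and 0.07 (early osteoblast) had the same adjusted p there, so a lost call does not grade the lists. The largest difference among named genes was in Ccl3, a chemokine of myeloid cells, 14.6-fold lower (7.39 ± 0.39 against 11.26 ± 0.44, SD, n = 2 arrays per group). Slc7a11, the cystine transporter, was 13.0-fold higher (9.38 ± 0.25 against 5.68 ± 0.48, SD) on the brighter of its 2 probe sets; the other lay below the detection floor and differed by 0.05, and the mean of both by 1.87. Col1a1, the main collagen of bone, differed by -0.01 and Alpl by -0.03 on the brighter of its 2 probe sets (0.18 on the other). In replicate 2 both genes held exactly equal mutant and wild-type values on these probe sets. How such equal values arose is not known here, so they do not establish that either gene was unchanged.

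Across 17841 genes, 0 passed the adjusted threshold in limma, and the smallest adjusted p was 0.312. At unadjusted p under 0.05 there were 707 genes (3.96% of those tested), and 461 of the tested genes also differed by 1.5-fold, 236 higher and 225 lower. The offset between replicates widens the residual spread of this fit, so these counts do not measure how many genes differ. The 461 became 273 without wild-type replicate 1. With the replicate number as a block, 0 genes passed the adjusted threshold and 2319 the unadjusted p; an intensity trend in the variance called 49. Quantile normalization again with the block, a fit chosen after the data were seen, called 399. Within replicates, 469 genes were at least 1.5-fold apart in the same direction in both, 263 higher and 206 lower, and 0 were that far apart in opposite directions. Differences of replicate 1 and replicate 2 correlated across genes (Pearson r = 0.85, Spearman rho 0.66), where genes are not independent of each other, and 4583 genes had exactly equal mutant and wild-type values in both replicates.

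**Figure D1:**
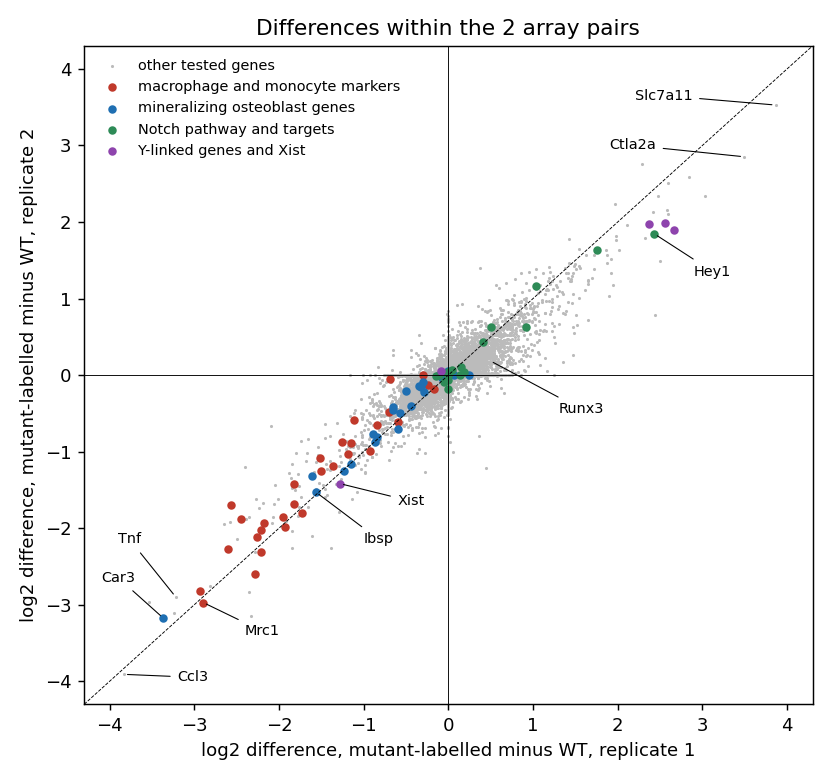
Log2 difference between mutant-labelled and wild-type arrays within replicate 1 (horizontal) and within replicate 2 (vertical) for each tested gene, with 4 gene lists coloured and equality dashed. Macrophage genes lie at the lower left, down to Mrc1 at -2.90 and -2.97; Hey1 lies at 2.43 and 1.85.

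Macrophage and monocyte markers fell as a list (limma camera, adjusted p = 1.3e-55, median log2 difference -1.34 over 32 genes). With an estimated correlation the adjusted p was 0.856. Of the 32 genes, 30 were lower in both replicates, 0 were higher in both, and 25 were at least 1.5-fold lower in both; list medians were -1.51 within replicate 1 and -1.22 within replicate 2. Adjusted over the list alone, 23 members passed (18 with the replicate block), against 0 over all genes tested. Mrc1, the mannose receptor, was 7.64-fold lower, Ms4a7 7.36-fold, Mpeg1 4.57-fold and Lyz2, the lysozyme of myeloid cells, 3.41-fold. Other genes with the largest differences included Vsig4, a complement receptor of tissue macrophages, at -3.17, the cytokine gene Tnf at -3.06, Wfdc17 at -2.78, Lilrb4a at -2.74, Lyz1 at -2.44 and Adgre1, which encodes F4/80, at -2.44. Markers of osteoclasts, which share a lineage with macrophages, did not pass as a list (median -0.01 over 17 genes, adjusted p = 0.855). Its smallest p belonged to Atp6v0d2, at -1.24.

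Genes of mineralizing osteoblasts also fell as a list (camera, adjusted p = 1.95e-18, median -0.42 over 25 genes), alongside the fall in macrophage markers; with an estimated correlation the adjusted p was 0.856. Of the 25, 19 were lower in both replicates and 1 was higher in both. Adjusted over the list alone 8 members passed (9 with the replicate block), against 0 over all genes: Car3, Panx3, Ibsp, Mepe, Slc13a5, Ifitm5, Dmp1 and Phex. Ibsp, the bone sialoprotein gene, was 2.92-fold lower (11.48 ± 0.25 against 13.03 ± 0.23, SD, n = 2), with -1.56 and -1.53 within the replicates. Panx3 was at -1.24, Mepe at -1.16 and Car3, carbonic anhydrase III, which adipocytes also express, at -3.27 on the brighter of its 2 probe sets (-2.48 for the mean of both). Bglap, which encodes osteocalcin, differed by -0.54 (SE 0.21, adjusted p = 1), with -0.57 and -0.50 within the replicates. It passed after quantile normalization again with the replicate block, a fit chosen after the data were seen (limma, adjusted p = 0.0479). Its values ran from 5.19 to 6.06, close to the floor of 4.71, so this row is a dim readout of the gene. Osteocyte genes fell with a small median of -0.08 over 25 genes (adjusted p = 2.3e-06, and 0.856 as the adjusted p with an estimated correlation), led by Ptprz1 at -1.53 and Mepe, both past the threshold over the list alone, where 4 passed with the replicate block. The median of that list ran from -0.246 to -0.00292 with an array left out, where that of all tested genes ran from -0.153 to 0.151. The list median lay below that of all tested genes each time.

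**Figure D2:**
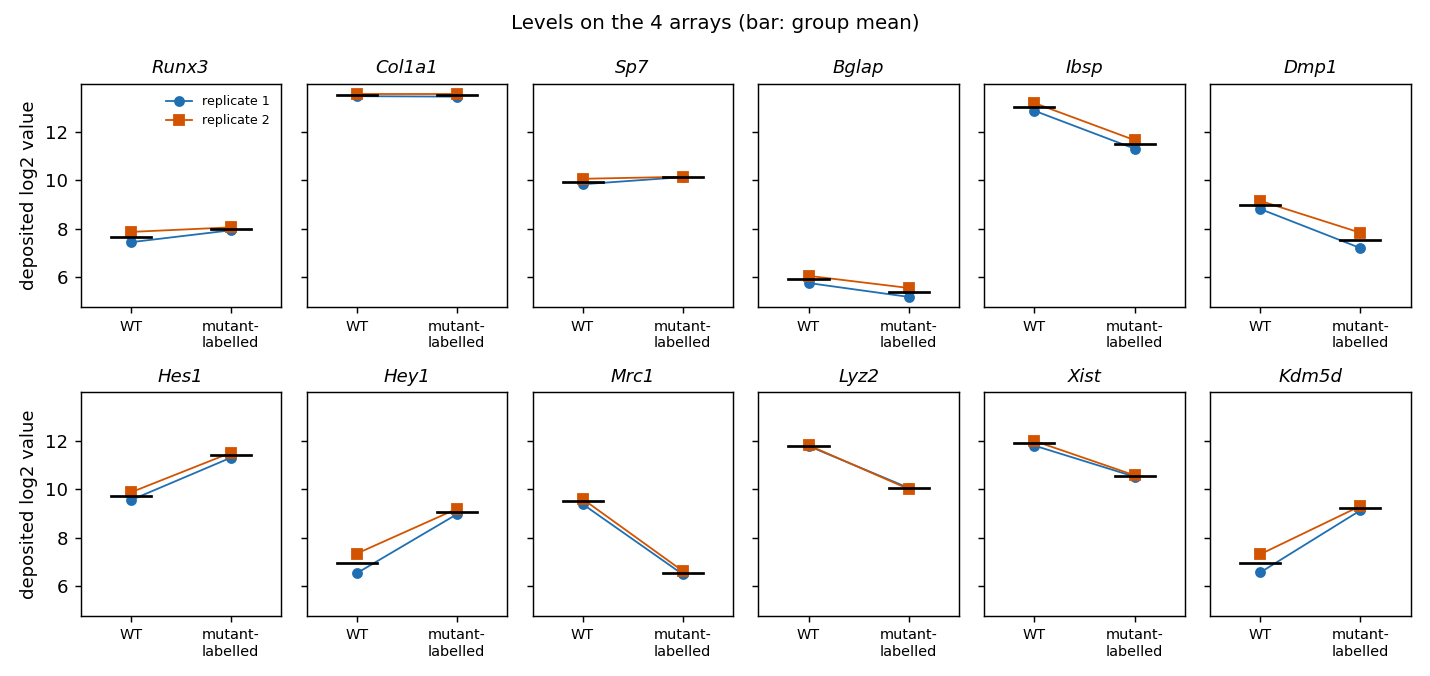
Deposited log2 values of 12 genes on the 4 arrays; lines join the arrays of the same replicate number and bars mark group means. Ibsp, Dmp1, Mrc1 and Lyz2 are lower and Hes1, Hey1 and Kdm5d higher on both mutant-labelled arrays, while Runx3 is not lower.

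Transcription factors and early markers of osteoblasts went the other way, with a small shift (median 0.07 over 19 genes, camera adjusted p = 0.00353, and 0.856 as the adjusted p with an estimated correlation). Hey1, which is also counted in the Notch list, was at 2.14, Zfp521 at 0.58 and Id4 at 0.73. Over the list alone 0 members passed (1 with the replicate block). Sp7, which encodes osterix, differed by 0.19 (SE 0.14). Without mutant-labelled replicate 1 the list's adjusted p was 0.345, and without wild-type replicate 2 it was 0.0677. Collagens and their processing enzymes did not pass (median -0.02 over 30 genes, adjusted p = 0.178), with Col14a1 at -1.07 the member of smallest p.

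Cell cycle genes were lower. The G2 and M phase list fell, with a median log2 difference of -0.33 over 32 genes (camera, adjusted p = 6.6e-18), with 28 lower and 0 higher in both replicates. The G1 and S phase list had a median of -0.34 over 29 genes (adjusted p = 2.97e-16), with 23 lower and 1 higher in both. Both had an adjusted p of 0.856 with an estimated correlation, and 0 members of either passed over the list alone, although 3 of the G2 and M phase list did with the replicate block. Mcm6 and Mcm3, subunits of the replicative helicase, were at -0.66 and -0.63, and the mitotic genes Kif2c and Bub1 at -0.56 and -0.51.

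Notch pathway genes rose as a list (camera, adjusted p = 1.93e-05, median 0.05 over 19 genes), and with an estimated correlation the adjusted p was 0.856. Hes1, Hey1 and Hey2, transcriptional targets of Notch, passed over the list alone, at 3.24-fold, 4.40-fold and 2.14-fold higher. The other 16 members did not; the ligand gene Jag1 was at 0.57. With the replicate block 0 members passed. The list median was -0.12 without wild-type replicate 1 and -0.09 without mutant-labelled replicate 2, while camera still called the list higher. It was 0.0102 after quantile normalization again and 0.0189 with every row tested. Leaving out an array leaves the offset between replicates in the difference: the median of all tested genes was then -0.15 and -0.13.

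The adipocyte and chondrocyte lists were called lower, with 11 of 21 and 14 of 25 genes lower in both replicates. The adipocyte list had a median of -0.11 and a mean of -0.50 (camera, adjusted p = 3.07e-07, and 0.856 as the adjusted p with an estimated correlation), with Car3, the fatty acid carrier Cd36 (-2.10) and lipoprotein lipase Lpl (-1.53) past the threshold over the list alone. Cd36 and Lpl are also made by macrophages. The chondrocyte list had a median of -0.17 (adjusted p = 1.8e-06, and 0.856 likewise), with Col10a1 at -2.05 and Cnmd at -1.22 against Prg4, lubricin, at 0.87; 3 members passed over that list alone and 1 with the replicate block. Without mutant-labelled replicate 1 the adipocyte median was 0.08 and the chondrocyte median -0.01, where that of all tested genes was 0.15, and without mutant-labelled replicate 2 they were -0.47 and -0.49. Camera called both lists lower in each case. Endothelial markers did not pass (median 0 over 21 genes, adjusted p = 0.2), although Flt1 at 1.36, Cdh5 at 1.49 and Lyve1 at -0.70 passed over the list alone, and 0 members with the replicate block.

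Of 4 tested genes on the Y chromosome 3 were higher, and Xist, the RNA of the inactive X chromosome, was lower (camera over these 5 genes, adjusted p = 0.00355, and 0.856 as the adjusted p with an estimated correlation). Eif2s3y was 4.85-fold higher, Kdm5d 4.83-fold and Uty 4.51-fold, while Xist was 2.55-fold lower, with -1.28 and -1.42 within the replicates. These 4 passed over the list alone, and 1 with the replicate block. Sry, the remaining Y-linked gene, was at -0.02, with -0.09 and 0.05 within the replicates. It was dim, at 4.94 and 5.03 in replicate 1 against the floor of 4.71. Without the dim-gene filter the list held 7 genes and its median went from 2.17 to 0.0415. With the replicate block the adjusted p of the list was 0.325. The macrophage, mineralizing osteoblast and cell cycle lists were lower on the same arrays.

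Smaller shifts were called for 4 further lists, each with an adjusted p of 0.915 under an estimated correlation. Respiratory chain genes had a median of -0.07 over 35 genes (camera, adjusted p = 0.00355), which became 0.508 without wild-type replicate 1 and 0.425 without mutant-labelled replicate 2. Housekeeping genes had a median of -0.06 (adjusted p = 0.0349), led by Tfrc at -0.70, and lost the call without the same arrays (0.722 and 0.635), after quantile normalization again (0.168) or median centring (0.0617), with the floor at the median of all rows (0.0571) and with every row tested (0.0788). Immediate early genes had a median of 0.05 (adjusted p = 0.00719), led by Atf3 at 1.20, and smooth muscle markers a median of 0.07 (adjusted p = 0.00719), led by Mylk at 0.77. Without mutant-labelled replicate 1 these became 0.262 and 0.399, and without wild-type replicate 2 both became 0.285. Medians turned to -0.08 and -0.02 without wild-type replicate 1, where that of all tested genes was -0.15, so both lists stayed above it. With the replicate block 9 immediate early genes and 7 smooth muscle markers passed over their lists alone, against 1 and 0 without it. With every row tested these lists lost their call (0.0587 and 0.0788).

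**Figure D3:**
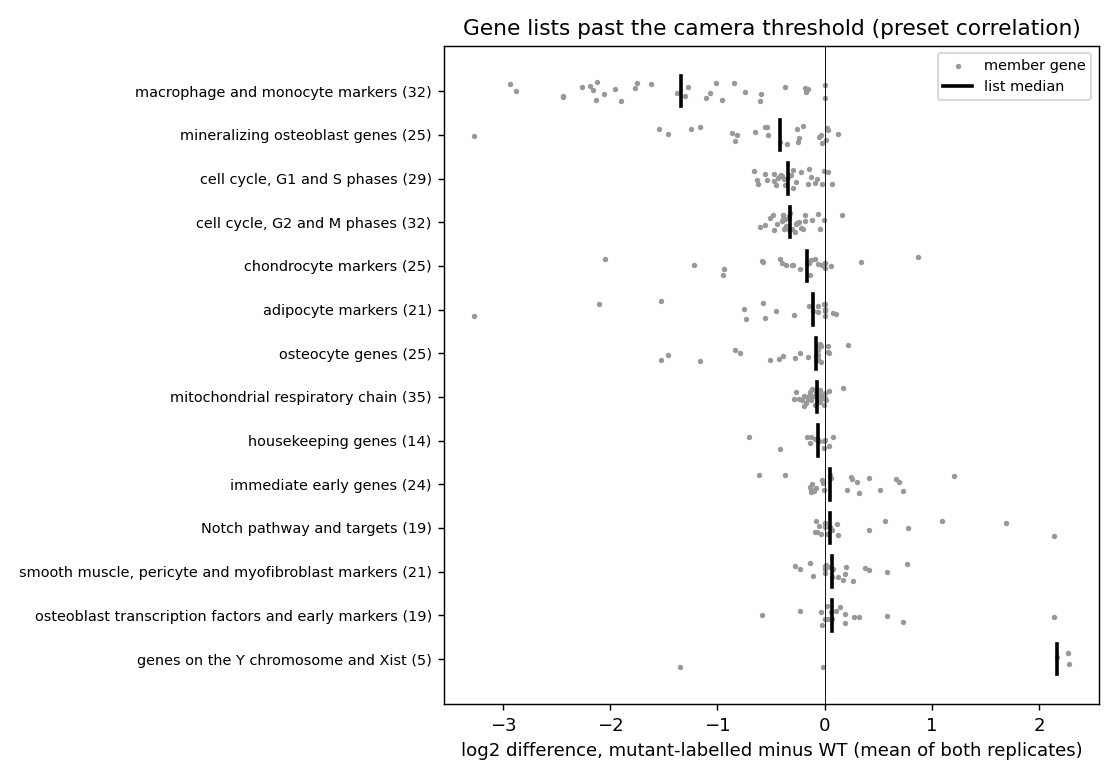
Log2 difference between mutant-labelled and wild-type arrays, averaged over both replicates, for each member (points) of the 14 lists past the camera threshold at the preset correlation, with list medians as bars and the number of tested genes in brackets. The macrophage list has a median of -1.34, and most other medians lie near 0 with a few members far from it.

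Of the 39 lists, 14 passed at the preset correlation, 5 higher and 9 lower, and 0 passed with an estimated correlation or with fry, where the smallest adjusted p was 0.366. With the replicate block fry called 13 lists, while camera with an estimated correlation called 0. In that fry test the macrophage, mineralizing osteoblast, G2 and M phase and Notch lists were each at adjusted p = 0.0428. The G1 and S phase list (0.0958) and the adipocyte list (0.109) did not pass. The smallest value, 0.000424, was shared by the cholesterol synthesis list and the epithelial list, whose median was 0. Other genes with the largest differences were Ctla2a (9.01-fold higher), Iqcn (6.56-fold), Ms4a4d (5.86-fold), Thsd4 (4.83-fold), Crispld2 (4.27-fold), Ppp4r4 (4.17-fold) and the histone gene H4c14 (3.72-fold), and on the lower side C1rb (9.49-fold) and the protease gene Mmp3 (4.99-fold). The rule that named these 9 required an unadjusted limma p under 0.01 without the replicate block. With it the unadjusted limma p ran from 0.00225 (Ms4a4d) to 0.0326 (Ppp4r4). In both fits 0 passed the adjusted threshold. All 9 passed after quantile normalization again with the replicate block, and 5 passed with the intensity trend. Of all genes named by the rule, 23 and 15 passed in these fits.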

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

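Of the tests below, those of RNA without a poly(A) tail were chosen only after the result was seen, and the test on histone features was added last, when the histone counts were already known. After their values were seen, the reading of the genomic DNA test was changed from excluded to open, and the test of signal loss was set aside and then restored as first written. Tests of a smaller share of every other cell type and of normalization of sex-linked genes were dropped after their values were seen, because their outcome was fixed or their form had been changed.

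Rows with no gene symbol, which the comparisons above did not use, held a signal above the wild-type arrays. Of these, 23 were at least 4-fold higher on the mutant-labelled arrays within both replicates. The longest run of neighbouring feature numbers held 10 of them, with mean log2 differences from 2.80 to 6.92. In 9 of these 10 a wild-type value lay below the floor of 4.71, so these differences are partly against background; with wild-type values raised to the floor they ran from 1.69 to 6.47. Among rows at least 2-fold apart in both replicates, 142 of 177 unnamed rows were higher (80.2%), against 88 of 192 rows with 1 symbol (45.8%). Genomic DNA in the RNA labelled mutant stays open: 49.7% of 165 receptor features with the same sign in both replicates were higher (95% interval 41.8 to 57.6), and processing may have removed a rise shared by all silent features. More RNA without a poly(A) tail among the labelled RNA may contribute: of features with the same sign in both replicates, 91.8% of 49 for small nucleolar RNA were higher, against 46.0% of 6423 other genes (Fisher's exact test, two-sided, p = 1.76e-11). That test treats features as independent, so its p measures no spread between cultures. The small nucleolar RNA features were counted without the detection floor, the other genes above it. Features shared by several histone genes, many of whose mRNAs also lack the tail, were higher in 63.0% of 27 with the same sign in both. That share falls between the bounds set for that test and leaves it open. The 10 lower features include H2al1 variants (-0.17 and -0.42), for which a missing tail was not established here. They also include pairs of features with identical differences. Both lower the share. Several higher features list the same set of histone genes as each other, which may raise it, so it is not a clean measure in either direction. What the unnamed rows measure is not known here, and a biological effect of the genotype on them was not tested.

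Macrophage and monocyte markers were lower, with 30 of 32 lower in both replicates. A general loss of signal at the level of these genes would lower other genes of that level too, but 3454 of them had a median of 0 (quartiles -0.06 and 0.06), and 25 reached the marker median of -1.34. Of 11 lists of other cell types, camera called chondrocytes (median -0.17) and adipocytes (-0.11) lower and smooth muscle (0.07) higher, and 0 of these kept the call with an estimated correlation; shares of other cell types stay open. A smaller share of macrophages in the mutant-labelled cultures may underlie the pattern: of a second list written before it was tested, 72.5% of 51 measured genes were lower in both replicates and 0 were higher, short of the 80% set in advance. Among the most abundant markers of the first list, Mrc1 was 7.64-fold lower, Lyz1 5.43-fold, Ctss 4.38-fold, Fcer1g 4.35-fold, C1qb 3.74-fold, Lyz2 3.41-fold, Cd68 1.68-fold and Gpnmb, which osteoblasts also express, 1.14-fold. The number of macrophages and an effect of the genotype on these genes cannot be told apart, since no cell counts were used.

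The Y-linked genes Eif2s3y, Kdm5d and Uty were higher and Xist was lower on both mutant-labelled arrays, while Sry was at -0.02. Sry read 4.94 (mutant-labelled) and 5.03 (wild type) in replicate 1, close to the floor of 4.71, and 6.28 and 6.22 in replicate 2. A gene this dim weighs little on the pattern. After quantile normalization again Eif2s3y, Kdm5d and Uty were at 2.22, 2.22 and 2.13, and after median centring at 2.28, 2.28 and 2.18. Medians over all rows were already close, at 5.50 (mutant-labelled) and 5.45 (wild type) in replicate 1 and 6.08 and 6.05 in replicate 2. These steps could therefore move the values little, so they do not test normalization as the source. Differences in array median of that size are too small to be the source for these 3 genes. Xist was not followed under these settings, and other effects of processing stay open. A larger share of cells from male pups in the mutant-labelled cultures may underlie the pattern, and 2 of the 3 measured genes that escape X inactivation, Kdm5c at -0.18 and Kdm6a at -0.06, were lower in both replicates; Ddx3x was equal in replicate 2. With 3 genes this test cannot decide. The sex of the pups is not in the labels, so sex and genotype cannot be told apart for any gene that depends on sex.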

How the results depend on the processing

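Fits that combine the replicate block with another choice, the count within both replicates and the count without macrophage genes were chosen after seeing the data; the others were fixed before. Genes past adjusted p numbered 0 in the main analysis and under every alternative fixed beforehand, replicate block and each array left out included, except the intensity trend (49). Quantile normalization again with the replicate block gave 399, and with robust hyperparameters and intensity trend added 39. All 49 trend calls were at least 1.5-fold apart in both replicates and 43 were also among the 399. The 461 genes past unadjusted p and 1.5-fold became 994 with every row tested (65.8% higher, more features being tested) and 214 at 2-fold, and ranged from 273 (without wild-type replicate 1) to 578 (without wild-type replicate 2), 34.8% to 69.9% of them higher, with an array left out. The 469 genes apart in both replicates became 1149 with every row tested, 187 at 2-fold and 426 without the genes of both macrophage lists. Lists called (14) became 0 with an estimated correlation and 0 with fry, 16 with the replicate block (13 with fry and the block), and 13 to 15 with an array left out; the cause was not tested. With the replicate block the list of Y-linked genes and Xist lost its call. Calls were gained there by mitochondrially encoded genes (camera, adjusted p = 0.00128), cholesterol and fatty acid synthesis (0.0121), and small leucine-rich proteoglycans and elastic matrix (0.0255). The Runx3 difference stayed above 0, from 0.13 to 0.55 with an array left out. Signs turned for small differences only. With an array left out the offset between replicates stays in the difference, and the median of all tested genes then ran from -0.153 to 0.151. Col1a1 was 0.0245 after quantile normalization again, 0.0245 with the replicate block added and 0.0245 with robust hyperparameters and intensity trend as well, and ran from -0.0688 to 0.0491 with an array left out. Alpl was 0.0736 with the mean of its probe sets and ran from -0.0807 to 0.0112 with an array left out; Cbfb ran from -0.144 to 0.0891 and Runx1 from -0.14 to 0.278. In all, 11 values of named genes reversed, 45 came to pass the threshold and 501 stayed on their side.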

Other observations

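The tests in this part were written before their results were seen; the genes of the next paragraph were chosen after their values were seen, as those at least 2-fold apart in both replicates and outside the gene lists, and are given as values only.

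On the higher side of the mutant-labelled arrays, Hspa1a had a log2 difference of 2.68, Irf1 1.49 and Socs3 1.15. Anxa8 was at 1.87, the retinol receptor Stra6 at 1.60, the phosphodiesterase Pde5a at 1.64, the endothelin receptor Ednrb at 1.45 and tenascin N, Tnn, at 1.40. On the lower side were Folr2 at -2.30, F13a1 at -1.91, Stab1 at -1.66 and the secreted Wnt antagonist Frzb at -1.60.

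A segment around Runx3 carried over from another mouse strain could add differences near the gene. Among the 200 nearest tested genes, 10 were at least 1.5-fold apart in both replicates (5.00%), against 459 of 17640 others (2.60%), a ratio of 1.92 (Fisher's exact test, two-sided, p = 0.0438). The ratio lay below the 3 times set in advance and above the 1.5 times set for no enrichment, and the interval of the odds ratio, 0.92 to 3.74, includes both bounds. The 10 genes include C1qa, C1qb, C1qc and Laptm5, which are macrophage markers. The test also treats genes as independent, so it leaves the hypothesis open.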
